A study of Xenopus laevis with 6 samples.

How the data were processed

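Bulk RNA sequencing of Xenopus laevis animal pole explants at stage 17 was analysed in 6 libraries, 3 from explants given K02288 and CHIR99021 from stage 9 to 17 and 3 from explants given the vehicle DMSO over the same period. Groups were taken from the sample labels. The labels describe the samples as replicates without naming clutches, embryos or explant numbers per library, so p-values measure the spread between these libraries, which may be technical.

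The deposited table holds, per the file headers, a mean signal per gene, a log2 fold change with its standard error, a Wald score, p-values and adjusted p-values, and a column of normalized counts for each library. DESeq is named without a version per the submitters' processing notes. The aligner, the counting program, the genome build and the annotation are not given in the sources used here. The authors' signal per library is a count of reads per gene divided by a size factor of that library: 100% of the 184429 values above 0 were whole multiples of the value of 1 read, within 0.01 reads, so whole reads were recovered. Genes are named by symbol with the suffix L or S for the homeologs of this allotetraploid species. The table holds 49281 genes, of which 14473 end in L and 11099 in S, and 11214 have no read in any library. Of the symbols, 62.4% matched the RefSeq gene table supplied beside the data, which was not used further. Coordinates are not printed, because the sources name no build.

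Left out of library sizes and tests, except in the repeat of the authors' fit, were 5 summary rows of the read counter. As a percentage of the gene reads and the reads of these classes together, reads in no gene made up 10.9% to 12.8%, ambiguous reads 0.439% to 0.716%, and reads aligned to more than 1 place 4.93% to 5.91% in 5 libraries and 11.1% in DMSO library a. Reads of L and S copies or of other near-identical genes that fall in this last class are lost to both copies, so levels of such genes are uncertain. In 1 row the cells were shifted by 1 position because the gene name had been broken in 2, and it was mended by rejoining the name. Another line was empty.

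The plan, fixed before the data were examined, named a negative binomial test for raw counts and a fallback for normalized values. Since the deposited values are normalized, the fallback was used: limma with trend on log2(normalized count + 1), genes with a mean of at least 10 over the 6 libraries, and Benjamini-Hochberg adjusted p under 0.05. Fold changes are therefore on the log2(value + 1) scale, which understates changes of low genes. Tools were limma 3.58.1, edgeR 4.0.16 and DESeq2 1.42.0 in R 4.3.3, with Python 3.11.15, scipy 1.17.1 and matplotlib 3.10.9 for summaries and plots. To repeat the authors' fit, DESeq2 was run on the recovered reads with the summary rows of the read counter kept in. It gave a log2 fold within 0.01 of the authors' value for 100% of 38067 genes. The same 13769 genes had a DESeq2 adjusted p under 0.05.

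Gene lists were written before the data were examined: 25 lists of 464 entries and 439 different symbols, 25 of which stand in more than 1 list. They cover neural plate border specifiers, neural crest specifiers, neural crest migration and adhesion, pigment cells, epidermis, multiciliated cells, ionocytes, goblet and small secretory cells, pan-neural genes, anterior neural and eye field, midbrain and hindbrain, posterior body axis, preplacodal and sensory placode genes, cement and hatching gland, BMP targets, canonical Wnt targets, early Wnt dorsal organizer genes, mesoderm, endoderm, blastula pluripotency, FGF and ERK response, Notch pathway, stress and p53 response, cell cycle and reference housekeeping genes. Both homeologs of a symbol were counted as members. Lists were tested with camera, two-sided, with a preset inter-gene correlation of 0.01, and adjusted over the 25 lists. Genes named in the text follow a rule fixed at the same time: in each direction the 10 genes with the largest log2 fold among those past the threshold with a mean of at least 50 and non-overlapping groups, in each list up to 4 members with the smallest adjusted p and up to 2 past the threshold in the other direction, and 22 symbols always, both homeologs where tested (sox2.S was not). Some genes that the rule names are not reported here. Genes named outside this rule are marked as chosen after their values were seen.

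The fit was tested on simulated data made from the means and spread of these libraries. With a small set of genes changed, the median fitted log2 fold was 0.98 for a true change of 1 and 1.94 for a true change of 2. The share of them called was 0% of 98 genes and 38.5% of 96, with 3 false calls among 22609 unchanged genes, since few changed genes make the adjustment strict. With 50% of genes changed, closer to these data, 52.2% of 5560 genes changed by 1 and 86.7% of 5777 changed by 2 were called, and 2.43% of the calls were false. Of the simulated lists, 5 of 5 changed and 0 of 20 unchanged lists were called. Their genes were drawn independently and few genes were changed. The simulation therefore does not test the preset correlation where genes of a list vary together. Estimated correlations in the real lists reached 0.746, in cement and hatching gland genes.

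Gene reads per library ranged from 33706389 to 43155031. A group with no read of a gene is given a floor of 3 reads over its 3 libraries, and fold changes against it are written as lower bounds. With 1 to 3 reads in a group the ratio of reads is given with an exact 95% interval. Floors and intervals cover counting error only. With a library left out, the floor is 3 reads over the libraries that remain, so ratios also move with the depth left.

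The libraries of both groups carry the letters a, b and c in the column headers. These letters, not the labels, are the source of the pairing tested as a replicate block. Deviations from the group means correlated across genes between libraries of the same letter (r = 0.326 for a, 0.402 for b and 0.319 for c), so the letters were taken to pair the libraries. Pairs of different letters gave r from -0.228 to -0.0905. Deviations within a group sum to 0, so these negative values follow from the positive ones and add no support. The main fit, as planned, had no block and so ignores this pairing. Alternatives tried were other pseudocounts, filters, scalings, tests, thresholds, homeologs summed, the block, and each library left out in turn.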

Results

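The animal pole of the Xenopus blastula holds pluripotent cells that form epidermis when explanted without further signals. Explants were treated from stage 9 to stage 17 with K02288, an inhibitor of BMP type I receptors, together with CHIR99021, a GSK3 inhibitor that activates canonical Wnt signalling, or with DMSO. Per the labels the treated explants were taken as reprogrammed to neural crest and the controls as epidermal, and the study was designed to induce a neural crest state with this pair of compounds. Transcripts were measured by bulk RNA sequencing in 3 libraries per group. Gene reads numbered 43155031, 37299139 and 33706389 in DMSO libraries a, b and c, and 35784464, 36618892 and 35187635 in K02288/CHIR libraries a, b and c. The 100 most abundant genes of a library took 29.8% to 31.3% of gene reads in controls and 23.8% to 24.6% in treated explants. Along the first principal component, which held 80.8% of the variance, treated library a lay at 106 and treated libraries b and c at 187 and 196, against -170 to -156 in controls.

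In treated explants, border and neural crest regulators that had few or no reads in controls were among the largest rises, and genes of the epidermis, multiciliated cells and ionocytes fell as lists. With an estimated correlation the adjusted p was 0.400 for epidermis, 0.395 for multiciliated cells and 0.400 for ionocytes. Of the 10 largest rises, 7 belonged to foxd3, pax3, zic1 and lmx1b.1, transcription factors of the neural crest, the neural plate border and the dorsal neural tube. The other 3 were xa-1.L, aqp3.L, a water and glycerol channel, and astl2f.S, an astacin-like protease. The 10 largest falls included both homeologs of szl, a secreted regulator of BMP signalling, both homeologs of ca2, a carbonic anhydrase, and the transporters slc26a4.3.L, slc26a4l.L, slc6a3.S and atp12a.L, with tbc1d24.2.L. Of these, slc26a4l.L passed by limma (adjusted p = 0.00932) and missed the threshold in the edgeR test (adjusted p = 0.0507). For example, val.L had 18337 ± 8289 normalized counts in controls (SD, n = 3) and 3 reads over the treated group, a ratio of 19836 (95% interval 6787 to 96190), which was 39984 without treated library a and 12939 without b.

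Across the genome, 12806 of 22932 tested genes (55.8%) changed by limma-trend with an adjusted p under 0.05, 5995 of them higher and 6811 lower in treated explants. A change of at least 2-fold was fitted for 3643 higher and 5585 lower genes. The groups did not overlap for 12692 of the changed genes, and for 64.9% of all tested genes, where chance gives 10%. Upper quartile scaling moved the median log2 fold of all genes from 0.01 to 0.30 and gave 8110 higher and 5604 lower genes, of which 5298 and 4698 changed by at least 2-fold, so that the excess of lower genes turned around in both counts. The count test of edgeR on the recovered reads called 12423 genes, 5972 higher and 6451 lower. Tested against a log2 fold of 1 with edgeR's glmTreat, 5654 genes passed.

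**Figure D1:**
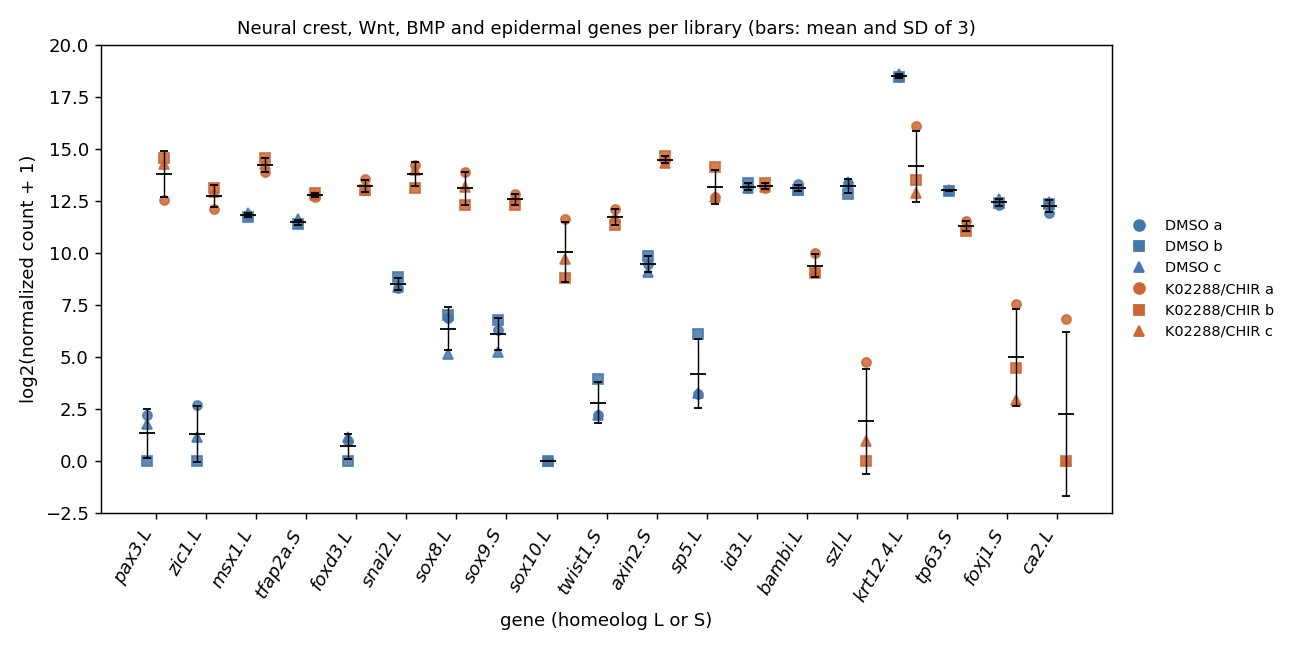
Normalized counts, as log2(value + 1), of 19 neural crest, Wnt, BMP and epidermal homeologs in each of the 6 libraries, with DMSO in blue and K02288/CHIR in orange, the symbols giving the library letter and the bars the mean and SD of 3 libraries. The reader should see sox10.L without a read in any control and at 445 to 3183 in treated libraries, and krt12.4.L at 69618 in treated library a against 11558 and 7509 in b and c.

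Neural plate border specifiers, which act at the edge of the neural plate, rose as a group: 21 of 28 tested homeologs were higher and 2 lower (23 and 2 adjusted over the list alone), with a median log2 fold of 2.06. The camera test gave an adjusted p of 2.8e-07, and an adjusted p = 0.383 with an estimated correlation. pax3.L went from 2.05 ± 1.87 to 16633 ± 9515 normalized counts and pax3.S from 4.02 ± 2.76 to 13057 ± 7855 (SD, n = 3), with a control mean of 1.24 for pax3.L without DMSO library a. zic1.L rose by 11.43 ± 0.67 and zic1.S by 11.03 ± 0.58 on the log2 scale (fold ± SE). The msx1 pair was expressed in controls and rose by 2.42 ± 0.18 for L and 2.03 ± 0.23 for S, and tfap2a by 1.05 ± 0.20 for L and 1.32 ± 0.12 for S. pax7.S was lower, with a log2 fold of -1.92 ± 0.64 (limma adjusted p = 0.0372). That call was lost with the replicate block (limma adjusted p = 0.0709), under upper quartile scaling (0.0628), and without DMSO library a (0.103) or b (0.12) or treated library a (0.0763) or b (0.1). The other lower member was id3.S, described with the BMP targets.

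Neural crest specifiers showed the largest median among the 25 lists at a log2 fold of 4.72, with 20 of 27 homeologs higher and 2 lower, the same counts adjusted over the list alone. The camera adjusted p was 2.47e-07, and the adjusted p = 0.383 with an estimated correlation. foxd3.S had no read in controls and 3725 ± 831 normalized counts in treated explants, while foxd3.L had 2 reads over the controls and 30648 over treated libraries, a ratio of 13570 (95% interval 3756 to 112057), or 8995 without DMSO library b. Both homeologs of sox10, a regulator of migratory crest, were without a read in controls and reached 1489 ± 1481 for L and 1459 ± 1291 for S in treated explants, with means of 641 and 722 without treated library a. Log2 folds were 6.75 ± 0.59 for sox8.L, 7.33 ± 0.77 for sox8.S, 4.72 ± 0.40 for sox9.L and 6.45 ± 0.38 for sox9.S. twist1, which promotes the mesenchymal state, rose by 8.03 ± 0.39 for L and 8.92 ± 0.51 for S. tfap2e rose by 6.41 ± 1.09 for L and 7.18 ± 0.23 for S. snai2.L, a repressor of cadherins, rose by 5.26 ± 0.30, whereas snai2.S had 92.3 ± 48.1 counts in controls and 172 ± 67.3 in treated explants and did not pass (limma adjusted p = 0.141). The 2 members that fell were myb.L at -4.61 ± 0.79 and myb.S at -6.06 ± 0.56. Treated library a held 3183 and 2934 counts of sox10.L and sox10.S, against 445 to 917 in b and c, and the fewest counts of pax3.L, 5931 against 19831 and 24137.

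Genes of crest migration and adhesion also rose together, with 21 of 28 homeologs higher and 2 lower (the same adjusted over the list alone) and a median log2 fold of 3.11. The camera adjusted p was 3.73e-07, and the adjusted p = 0.383 with an estimated correlation. The axon and crest guidance receptors epha4.L and epha4.S rose by 4.07 ± 0.15 and 6.83 ± 0.36, and nrp1.S by 9.52 ± 0.44. The fibronectin receptor subunit itga5.L rose by 2.12 ± 0.12. The chemokine receptor gene cxcr4.L fell by 1.32 on the log2 scale (limma adjusted p = 0.0155), a call lost without DMSO library b (adjusted p = 0.0507). itga5.S was the other lower member, at -0.64 ± 0.21 (limma adjusted p = 0.0363). Its call was lost under upper quartile scaling (adjusted p = 0.162) and without DMSO a (0.102), DMSO c (0.108), treated b (0.0765) or treated c (0.0654). Pigment cell genes did not pass as a list (camera adjusted p = 0.22; 5 of 11 higher, 2 lower, the same adjusted over the list alone). Members higher numbered 8 without treated library a, and 3 without DMSO a, treated b or treated c. The list's median in treated library a was 0.40 above the control mean, the lowest of the treated libraries, with 1.19 in b. Within it, mitf.S, the regulator of melanocyte genes, had 2 reads over the controls and 251 over the treated libraries, a ratio of 111 (95% interval 30.4 to 923). Its treated counts were 146 in library a, 52.5 in b and 35.3 in c. The ratio was 63.3 without treated a and 68.9 without DMSO a, and mitf.S was at least 49.3-fold higher without DMSO b, which held both control reads. pmel.S rose by 1.81 ± 0.27, and the receptor gene kit fell by 3.84 for L and 3.25 for S.

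**Figure D2:**
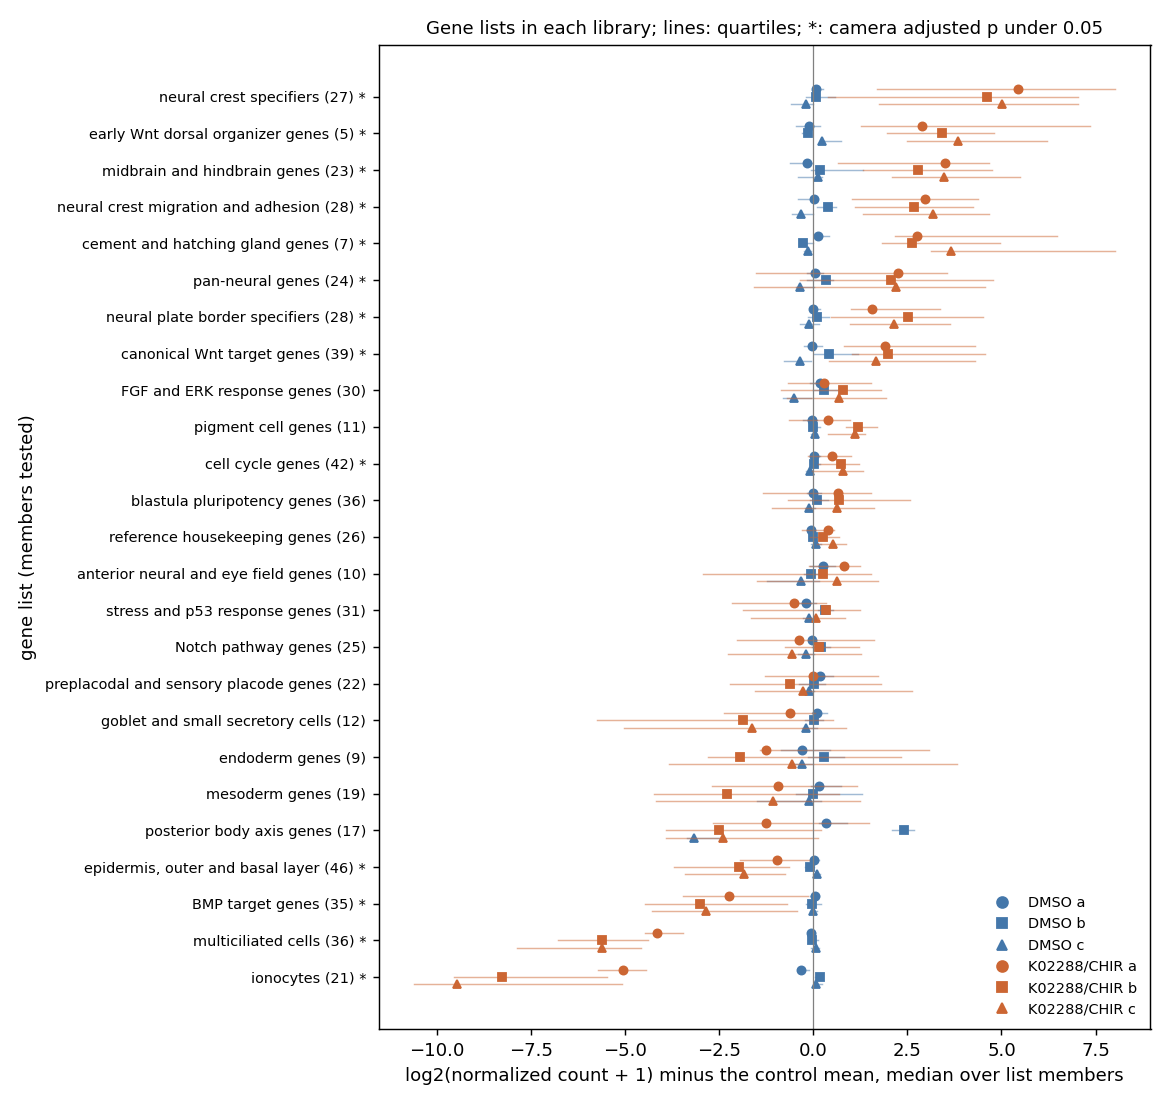
Median over list members of log2(normalized count + 1) minus the control mean, for 25 gene lists in each of 6 libraries, with quartile lines, library letters as symbols and the number of members tested in parentheses; a star marks a camera adjusted p under 0.05. Neural crest specifiers stand at the top with a median log2 fold of 4.72 and ionocyte genes at the bottom at -7.86.

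Epidermal genes of the outer and basal layer fell as a list, with 33 of 46 homeologs lower and 8 higher (34 and 8 adjusted over the list alone) and a median log2 fold of -1.78. The camera adjusted p was 0.000142, and the adjusted p = 0.400 with an estimated correlation. The larval keratin gene krt12.4.L fell from 370775 ± 25875 to 29562 ± 34749 normalized counts, with a treated mean of 9533 without library a, and krt12.4.S by 5.18 on the log2 scale (limma adjusted p = 0.0101; 0.0631 in the edgeR test). Regulators of epidermal fate fell as well: dlx3.S by 2.65, grhl1.S by 2.07, gata3.L by 5.03, tp63.L by 1.33 and tp63.S by 1.72. Among the members that rose were krt18.1.S by 5.35 ± 0.22, a simple epithelial keratin, and dlx6.S by 3.45 ± 0.30, a distal-less homeobox gene. Treated library a kept more of several of these transcripts. Its krt12.4.S count was 67579 against 3438 and 1906 in b and c. Without library a the list median was -1.94 with 36 lower and 8 higher members. Without treated library c 5 members were higher.

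Goblet and small secretory cell genes did not pass as a list, with 6 of 12 homeologs lower and 2 higher (the same adjusted over the list alone), a median log2 fold of -1.21 and a camera adjusted p of 0.381. foxa1.L, a regulator of small secretory cells, fell by 6.58, foxa1.S by 1.88 and otog.L, which encodes a mucin-related protein, by 4.71. pmp22.S rose by 3.40 ± 0.49 and xbp1.S, a regulator of secretory capacity, by 1.23 ± 0.31. Chosen after its values were seen, the mucin-like gene otogl2.L was at 421039 to 465424 counts in controls and at 88452, 5180 and 501 in treated libraries a, b and c.

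Genes of multiciliated cells and ionocytes, which are set into the larval epidermis, had the lowest medians of the 25 lists. In the multiciliated list 34 of 36 homeologs were lower and 2 higher (the same adjusted over the list alone), with a median log2 fold of -5.16, a camera adjusted p of 8.34e-10 and an adjusted p = 0.395 with an estimated correlation. foxj1, the regulator of motile ciliogenesis, fell by 6.04 for L and 7.44 for S, the axonemal genes dnai1.L by 4.40 and cfap52.L by 4.88, with tekt1.L at -4.58 ± 0.24 and enkur.L at -4.56 ± 0.23. The 2 that rose were tuba1b.S by 7.60 ± 0.44 and tuba1b.L by 3.12 ± 0.30, an alpha tubulin that other cells also use. Of 21 ionocyte homeologs, 20 were lower and 1 higher (the same adjusted over the list alone), with a median log2 fold of -7.86, a camera adjusted p of 6.07e-07 and an adjusted p = 0.400 with an estimated correlation. The anion exchanger gene slc4a1 fell by 4.16 for L and 4.59 for S, and esrrg.S, a nuclear receptor gene, was at -7.62 ± 0.74. A subunit gene of the vacuolar proton pump, atp6v0d2.S, had 33.0 ± 1.85 counts in controls and no read in treated libraries. The higher member was slc12a1.L, a call lost in 5 of 6 fits with a library left out, where the limma adjusted p was 0.0688, 0.0609 and 0.06 without DMSO a, b and c, and 0.0533 and 0.0744 without treated a and c. Without treated library a the list medians were -5.72 for multiciliated cells, with 33 lower and 2 higher, and -8.82 for ionocytes, with 19 lower and 0 higher.

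BMP target genes fell, with 26 of 35 homeologs lower and 6 higher (the same adjusted over the list alone), a median log2 fold of -2.80, a camera adjusted p of 0.000135 and an adjusted p = 0.383 with an estimated correlation. The BMP feedback genes bambi.L and bmper.L fell by 3.72 and 3.43, and ventx2.1.S by 2.15. bmp4.S, which encodes a BMP ligand, fell from 3686 ± 126 to 442 ± 135 normalized counts. ventx2.1.L rose from 808 ± 195 to 1730 ± 424 and both msx1 homeologs rose. id3.L, a direct target in many tissues, had 9334 ± 999 counts in controls and 9509 ± 929 in treated explants (limma adjusted p = 0.873), and id3.S was lower by a log2 fold of -0.55 ± 0.16 (limma adjusted p = 0.0246). The id3.S call was lost under upper quartile scaling (adjusted p = 0.159) and without DMSO a (0.0635), DMSO b (0.0512), DMSO c (0.0742), treated b (0.0792) or treated c (0.086). Canonical Wnt target genes rose, with 26 of 39 homeologs higher and 1 lower (the same adjusted over the list alone), a median log2 fold of 1.94, a camera adjusted p of 6.07e-07 and an adjusted p = 0.383 with an estimated correlation. axin2, a negative feedback gene, rose by 4.21 ± 0.29 for L and 4.99 ± 0.21 for S, tcf7.S by 6.09 ± 0.17 and fzd7.S by 4.40 ± 0.26. sp5.L rose by 8.96 ± 0.82, and sp5.S had 3 reads over the controls and 10440 over treated libraries, a ratio of 3082 (95% interval 1054 to 14946). That ratio was 1863 without treated library b and 1910 without DMSO a, and sp5.S was at least 2009-fold higher without DMSO b, which held all 3 control reads. The lower member was apcdd1.L, a Wnt inhibitor gene, at -2.93 ± 0.40. Lower members numbered 3 without treated library a and 2 without DMSO c or with the replicate block. All 5 tested homeologs of the early Wnt dorsal organizer list were higher (5 adjusted over the list alone), with a median of 3.39, a camera adjusted p of 0.00361 and an adjusted p = 0.383 with an estimated correlation. They were nog.S, nog.L, cer1.S and the otx2 pair, of which cer1.S and nog encode secreted antagonists. Of the list's 13 symbols 9 were in the deposited data, and no homeolog of sia1, sia2, chrd, gsc, frzb or the nodal3 genes was tested. Control means of nog.S, nog.L and cer1.S were 1.17, 7.36 and 9.91, so these reached the mean filter through the treated libraries. Such entry favours positive folds.

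Of 24 pan-neural homeologs 13 were higher and 6 lower (14 and 6 adjusted over the list alone), with a median log2 fold of 2.08, a camera adjusted p of 0.0178 and an adjusted p = 0.400 with an estimated correlation. That list call was lost without treated library b (camera adjusted p = 0.0762) and under upper quartile scaling (0.0515). sox11.L and zic2.L, transcription factor genes of early neural tissue, rose, the former from 129 ± 37.5 to 4645 ± 476 counts and the latter by 8.45 ± 0.52 on the log2 scale. Among members that fell, sox21.S was at -3.26 ± 0.36 and the Notch ligand gene dll1.L went from 431 ± 121 to 98.7 ± 16.9 counts. sox2.L, a marker of the neural plate, had 55.6 ± 11.8 counts in controls and 116 ± 77.2 in treated explants (limma adjusted p = 0.292), and passed without treated library a (adjusted p = 0.0127). Midbrain and hindbrain genes rose, with 17 of 23 higher and 2 lower (the same adjusted over the list alone), a median of 3.29, a camera adjusted p of 0.000142 and an adjusted p = 0.383 with an estimated correlation. irx1.L rose by 4.41 ± 0.50, and wnt1.L had 2 reads over the controls and 764 over treated libraries, a ratio of 338 (95% interval 93.3 to 2798). Its treated counts were 52.8, 173 and 490.2 in a, b and c, and the ratio was 164 without treated c and 209.7 without DMSO a. Anterior neural and eye field genes did not pass (camera adjusted p = 0.617; 3 of 10 higher and 1 lower, the same adjusted over the list alone), with a median of 0.37. Over the members still tested, the median was 1.12 without DMSO library a, 0.66 without DMSO c and 0.19 without treated c. Without treated library a 3 members were lower. otx2.L rose by 1.70 ± 0.37 and otx2.S by 1.57 ± 0.33, and the eye field gene six3.L fell by 4.42.

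Posterior body axis genes did not pass as a list, with 1 of 17 homeologs higher and 3 lower (1 and 2 adjusted over the list alone), a median of -1.62 and a camera adjusted p of 0.609. The list passed, lower, without DMSO library c (median -3.99 over the 21 homeologs then tested, adjusted p = 0.0217), with 10 of the same 17 lower. Without DMSO library b the median was 1.35 over the 10 homeologs then tested (adjusted p = 0.221), with 3 higher and 1 lower of those in the list before. Without treated library b 2 were higher. nkx1-2.L was without a read in controls and at 442 ± 259 counts in treated explants. hoxc6.S had 188 reads over the controls and 1 over treated libraries, a ratio of 212 (95% interval 37.6 to 8429). That ratio was 140 without DMSO b and 138 without treated b, and hoxc6.S was at least 46.7-fold lower without treated a. hoxc6.L and hoxa7.L were the other lower members, and the call of hoxc6.L (limma adjusted p = 0.0276) was lost without DMSO a (0.0781), treated b (0.0728) or treated c (0.0781). Controls differed among themselves: hoxa7.L was at 37.7, 183 and 4.94 counts in DMSO libraries a, b and c. Of the preplacodal and sensory placode genes, 6 of 22 were higher and 7 lower (6 and 8 adjusted over the list alone), with a median of -0.16, a mean of 0.33 and a camera adjusted p of 0.967. Without DMSO library a 4 were lower. eya2.S, a transcriptional coactivator gene of the placodes, fell by 4.07. Cement and hatching gland genes rose, with 6 of 7 higher and 0 lower (the same adjusted over the list alone), a median of 3.02, a camera adjusted p of 0.00249 and an adjusted p = 0.400 with an estimated correlation. The cement gland gene ag1.S rose by 3.02 ± 0.27 and agr2.L by 2.31 ± 0.36. These members were highest in treated library c, with 41973 counts of ag1.S against 22445 and 20405 in a and b.

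Mesoderm genes did not pass as a list, with 2 of 19 homeologs higher and 6 lower (0 and 6 adjusted over the list alone), a median of -1.29 and a camera adjusted p of 0.262. The median was -0.56 without DMSO library b, and no member was higher without DMSO a, DMSO c, treated b or treated c. hand2.L, a heart and lateral plate gene, fell by 6.95 and foxc1.L by 4.06. wnt8a.L, a Wnt ligand gene of ventral and lateral mesoderm, was higher by 3.94 ± 1.35 (limma adjusted p = 0.0425), which was lost without DMSO a (0.0655), DMSO c (0.11), treated b (0.117) or treated c (0.0917). tbxt.L was at 133 ± 135 counts in controls, and 3 reads were found over the treated group, a ratio of 151 (95% interval 51.2 to 733), or 78.9 without DMSO b and 295 without treated b. It did not pass by limma (adjusted p = 0.114) but passed with DESeq2 (adjusted p = 0.00706), in an edgeR fit with no filter (0.0137) and without DMSO library c (0.00192). tbxt.S was at 135 ± 120 and 229 ± 71.2 counts (limma adjusted p = 0.24). myod1.S, a muscle regulator, was higher at 36.6 ± 47.2 against 1.34 ± 1.60 (limma adjusted p = 0.0453), which was lost without DMSO a (0.102), DMSO b (0.0546), DMSO c (0.128) or treated c (0.0992). Its treated mean was 9.51 without treated b and its control mean 0.459 without DMSO b. Endoderm genes did not pass (3 of 9 higher and 4 lower, or 3 and 5 adjusted over the list alone; camera adjusted p = 0.684), with a median of -1.25 and a mean of 0.00. gata6.L rose by 3.08 ± 0.54, while gata4.S had 143 reads over the controls and 1 over treated libraries, a ratio of 161 (95% interval 28.5 to 6422), and was at least 35.6-fold lower without treated b, which held that read.

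Blastula pluripotency genes did not pass as a list, with 15 of 36 higher and 8 lower (16 and 8 adjusted over the list alone), a median of 0.63 and a camera adjusted p of 0.121. Its highest members, the foxd3 pair, also stand in the crest list, and ventx1.2.S fell by 3.88. FGF and ERK response genes did not pass (9 of 30 higher and 5 lower, or 8 and 5 adjusted over the list alone; camera adjusted p = 0.22). Lower members numbered 2 without DMSO b and 3 without DMSO a or treated c. The receptor genes fgfr4.L and fgfr1.L rose by 4.80 ± 0.25 and 1.92 ± 0.13, while spry1.S, a feedback inhibitor gene, fell by 3.32. Notch pathway genes went both ways (8 of 25 higher and 8 lower, the same adjusted over the list alone; camera adjusted p = 0.967), with hes4.L higher by 2.09 ± 0.18 and the ligand gene dlc.L lower by a log2 fold of -3.20 ± 0.35. Stress and p53 response genes did not pass (7 of 31 higher and 13 lower, the same adjusted over the list alone; camera adjusted p = 0.651). Without treated library a 12 were higher and 11 lower, and with the replicate block 11 were higher and 13 lower. Without DMSO a or treated b 4 were higher. junb.L fell by 2.96 and hspa5.S, a chaperone of the endoplasmic reticulum, rose by 1.79 ± 0.32. The medians of the placode, Notch and stress lists lay near 0 and were above it under upper quartile scaling, none of these lists passing. Over the members still tested, the placode median ranged from -0.81 without treated library a (19 of 22) to 0.19 without DMSO a (21 of 22), and was also above 0 without DMSO b (0.05) or c (0.17). Medians above 0 were found without treated a (0.06) or c (0.13) for Notch genes and without DMSO c (0.10) or treated a (0.10) for stress genes.

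Cell cycle genes rose, with 24 of 42 higher and 4 lower (25 and 4 adjusted over the list alone), a median of 0.70, a camera adjusted p of 0.000329 and an adjusted p = 0.400 with an estimated correlation. Members with the smallest adjusted p were subunit genes of the replicative helicase, mcm5.L at 1.86 ± 0.13, mcm2.L at 1.65 ± 0.13, mcm4.S at 2.25 ± 0.19 and mcm7.S at 1.37 ± 0.12. cdk1, the mitotic kinase gene, fell from 2574 ± 336 to 1234 ± 401 counts for L and from 2770 ± 229 to 1501 ± 207 for S. Lower members numbered 2 without DMSO b, DMSO c or treated c. Reference housekeeping genes did not pass as a list (11 of 26 higher and 4 lower, the same adjusted over the list alone; camera adjusted p = 0.129), with a median of 0.47. Higher members numbered 5 without DMSO a or treated c and 7 without DMSO b. actb.L fell by 1.91 and sdha.S by 1.23, while tbp.L and hprt1.L rose by 1.63 ± 0.20 and 2.15 ± 0.29.

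Where both the L and the S copy of a gene were called, most pairs went the same way. Among 5796 pairs with both copies tested, only 1 copy was called in 2101 and both were called in 2347, of which 2128 (90.7%) went the same way and 219 the opposite way, where independent calls at these rates would give 994 and 996. Log2 folds of L and S correlated across pairs with Pearson r = 0.70 and Spearman rho = 0.64. The largest absolute r in 100 shuffles of the partners was 0.0350, and genes are not independent replicates. In 89 of the 219 opposite pairs both copies moved by at least 2-fold, which was 57 pairs without DMSO c and 48 among pairs with a mean of at least 100 for both copies. Among the always named genes, ventx2.1.L and ventx2.1.S were such a pair. The count of opposite pairs was 135 without DMSO a, 135 without DMSO b, 122 without DMSO c and 127 without treated c.

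**Figure D3:**
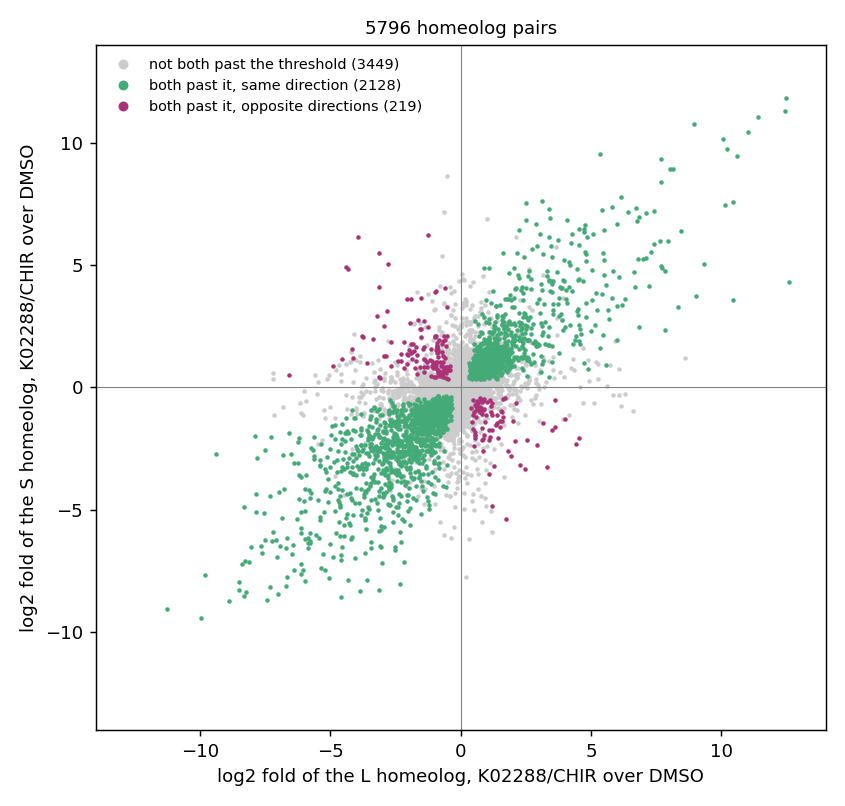
Log2 fold of the S homeolog against that of the L homeolog, K02288/CHIR over DMSO, for 5796 pairs, each point a pair. The 2128 pairs called in the same direction lie in the upper right and lower left, and the 219 called in opposite directions lie in the upper left and lower right.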

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

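The edgeR fits on recovered reads, TMM and upper quartile scaling, the block by column letter, the member counts of lists with a library left out and the ratios of low genes with a library left out were chosen after the data were seen, unlike the other alternatives. The count of changed genes stayed within 1.5 times 12806 in all settings but glmTreat, which asks for a log2 fold above 1 (5654 genes, 1995 higher and 3659 lower). It ranged from 9578 with homeologs summed, where 17242 genes were tested, to 13826 with DESeq2, and from 10502 to 12978 with a library left out. With the replicate block by column letter, a paired fit, 13798 genes passed. The authors' deposited table has 13769 genes at an adjusted p under 0.05 and 10986 under 0.01. No gene called in both fits changed sign in any setting. Genes were matched by name, so with homeologs summed (2561 shared calls) no entry ending in L or S was compared. A block by replicate number was not run, because the columns carry letters.

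The count of lists past the threshold was 13 with the preset correlation, 0 with an estimated one and 25 by fry's mixed test, which asks only whether members change. All 13 also passed fry's directional test, which asks whether members move in a shared direction without regard to other genes. So did goblet (fry adjusted p = 0.0113), mesoderm (0.00446), blastula pluripotency (0.000966), FGF and ERK response (0.0337) and housekeeping genes (0.029). The pigment, anterior neural, posterior, placode, endoderm, Notch and stress lists did not pass it. With an estimated correlation, the adjusted p was 0.383 for border, crest specifier, crest migration, midbrain and hindbrain, BMP, Wnt and organizer genes, 0.395 for multiciliated cells, and 0.400 for epidermis, ionocyte, pan-neural, cement gland and cell cycle genes. The pan-neural call was lost under upper quartile scaling (adjusted p = 0.0515) and without treated library b (0.0762, with 0.00326 to 0.0762 over the libraries left out). The posterior list passed without DMSO library c (0.0217, with a range of 0.0217 to 0.782). The cause was not tested. With homeologs summed, the cement gland and organizer lists had fewer than 5 members and gave no value. Homeolog pairs called in opposite directions numbered 122 to 237 with a library left out, the highest without treated library a.

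Of 153 named genes past the threshold, 131 passed in every alternative that tested them, and no named gene reversed. The block ended the call of pax7.S and changed no other call among the named genes and lists. In simulated data with 50% of genes changed, 52.2% of genes with a log2 change of 1 were called, so smaller changes are often missed with 3 libraries a group.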

Other observations

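The Hox paralog groups and the tests of treated library a and of the control libraries were chosen after the results were seen, as was the count of other splits for the gene lists, while that for genes was planned. Among 31 tested Hox homeologs, those of paralog groups 1 and 2 were mostly higher in treated explants (7 of 9 higher, 2 lower, median log2 fold 4.36) and those of groups 4 to 13 were lower or did not pass (0 of 15 higher, 6 lower, median -2.87). Of group 3, 1 of 7 was higher and 2 lower, with a median of 0.43. Chosen after their values were seen, hoxd1.L rose by 7.69 ± 1.00, hoxb2.S by 6.46 ± 0.36 and hoxb1.S by 4.36 ± 0.56, while hoxa3.L fell by 3.14. Log2 fold and paralog number had a Spearman rho of -0.54 across these 31 genes, which are not independent, and this describes the pattern without testing it. Levels of posterior Hox genes also differed among the controls, with hoxa7.L at 37.7, 183 and 4.94 counts in DMSO a, b and c. Several genes of groups 4 to 13 reached the mean filter through DMSO b. For example, hoxa9.L was at 23.0, 76.6 and 0 counts in DMSO a, b and c. Without DMSO b, hoxa7.L and hoxc6.L missed the filter, while hoxc6.S kept a log2 fold of -5.06. Entry through a high control favours negative folds. The median of -2.87 and the rho of -0.54 therefore cannot separate a fall in treated explants from this filter.

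Of the 219 homeolog pairs called in opposite directions, 4 are given here, chosen after their values were seen except for the L copy of apcdd1. cdh1.L, one of the copies of E-cadherin, rose from 31.7 ± 16.3 to 700 ± 208 normalized counts, while the far more abundant cdh1.S fell from 50236 ± 4828 to 12331 ± 2910. krt19.L fell by 4.56 and krt19.S rose by 1.18 on the log2 scale. vdr.L, a vitamin D receptor copy, fell by 3.95 and vdr.S rose by 6.13, and apcdd1.L fell by 2.93 while apcdd1.S rose by 2.50 (limma adjusted p = 0.0474).

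Treated library a kept more epidermal transcript than libraries b and c. Among genes with a control mean of at least 50 and at least 4-fold lower in b and c than in controls, the share of the control level left in library a over that in b and c had quartiles of 6.67% and 28.4% in 6 goblet and secretory genes and a median of 12.7% in 21 epidermal genes, against 3.37% in 30 multiciliated and 2.27% in 17 ionocyte genes. Whole control tissue or control reads mixed into the library would leave a like share of each, but the goblet median was 7.98 times the ionocyte median (two-sided exact permutation p = 0.0025 across genes). Genes of a library are not independent and the comparison was chosen after the results were seen, so this p-value is descriptive. Shares overlapped, at 0.63% to 39.4% in goblet genes and -1.56% to 4.35% in ionocyte genes. The unlike medians argue against such mixing as the whole cause only for the genes covered here. Weaker BMP inhibition stays open. The 26 BMP targets that fell in the fit without library a were higher in a than in treated b and c. The median difference was 1.11 log2 units (quartiles 0.43 to 1.57). These targets were picked as low in b and c, which favours higher values in library a, and epidermal cells may express them too. For weaker Wnt activation the values do not decide. The 27 Wnt targets that rose in the fit without library a gave a median of -0.0851 (quartiles -0.73 to 0.25). Picking them as high in b and c favours lower values in library a. A difference between clutches or layers of origin, which the labels do not give, was not tested.

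Posterior genes differed among control explants. Of 17 posterior homeologs 15 followed the order library b above a above c, with cdx4.S, chosen after its values were seen, at 700, 223 and 13.6 counts. This order was read from these same genes. Only 9 of the 17 reached the mean filter without DMSO library b, so the filter favours genes high in b and the count describes the pattern without testing it. If the controls held differing numbers of posterior mesoderm cells, mesoderm genes would follow the same order, and 8 of 19 (42.1%) did, where 15.0% of all tested genes do (one-sided exact binomial p = 0.00403; genes are not independent). Of those 8, the most abundant, tbxt.S and tbxt.L, had means of 135 and 133 counts in controls, while hand2.L, the most abundant of the list at 412, did not follow the order. Lists of other kinds followed it as often, with 12 of 25 Notch genes (48%), 11 of 24 pan-neural genes (45.8%) and 12 of 28 crest migration genes (42.9%), so the order is not particular to mesoderm. The mesoderm list medians were 0.16, -0.02 and -0.13 in DMSO a, b and c. These values do not decide whether such cells contribute.

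The count of 12806 changed genes was met by 1 of the 10 splits of the 6 libraries into 3 against 3, the real one, and the highest of the others gave 0 by limma. For the gene lists 4 of the 10 splits gave 13 or more past the threshold, and the highest of the others gave 14. The other splits gave 8 to 14 lists. A count of 13 lists by camera with the preset correlation therefore does not mark the real grouping. All other splits put treated and control libraries in the same group, which widens the spread, so few gene calls were likely there. With 10 splits no share under 0.05 can be had.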
